A study of Homo sapiens with 6 samples.

How the data were processed

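The series holds 6 RNA sequencing libraries of HepG2 cells, 3 transfected with a negative control siRNA and 3 with an siRNA against SF3A3 (50 nM, a lipid transfection reagent, 48 h). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a dual-mode mRNA library kit. Groups and replicate numbers were taken from the sample titles and the protocol. The treatment labels of knockdown 2 and 3 name SF3A4 and SF3A5, which reads like a running number, while the titles and the protocol give SF3A3, so these libraries were kept in the SF3A3 group. Overexpression and a second liver line that the series mentions were not analysed here.

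The submitters' processing notes name CASAVA 1.8.2, FastQC 0.11.9, HISAT2 2.0.5, StringTie 1.3.3, SAMtools 0.1.18, Picard 1.41 and the GRCh38 build, without their roles. The counting tool, the annotation release and the row filter are not given in the sources used here. Per the file headers, the authors deposited whole-number counts for each library, not normalized, and FPKM values for the same rows. The authors also deposited a mean of log2(FPKM + 1), a log2 fold change of knockdown over control, a p-value and a Benjamini-Hochberg adjusted p-value for each row. The ratio of count to FPKM of a gene varied between libraries, so the counts may be estimates from transcript coverage rather than counts of whole reads per gene. The table has 13451 rows, of which 12226 carry an Ensembl gene identifier and 1225 are models at 751 loci with the default prefix of transcripts assembled by StringTie. The assembled rows hold 2.23% of all counts. No row has a total under 124 counts or counts above 0 in fewer than 3 libraries, so rows below some level had been removed before deposit. Of the 12226 identifiers, 12166 were found in GENCODE release 29 (GRCh38), which gave coordinates, and 12151 are protein-coding there. The deposited table gives no symbol for 146 Ensembl rows. All per-sample columns were assigned to samples by their names.

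Library totals were 32037930, 31551141 and 35361182 counts in control 1 to 3 and 35283764, 34200307 and 31272558 counts in knockdown 1 to 3. Replicates were compared by a chi-square test of their counts over rows. The chi-square per degree of freedom was 12.3 to 20.8 between controls, 14.4 between knockdown 1 and 2, and 56.1 and 53.5 between knockdown 3 and knockdown 1 and 2, so no 2 libraries agree within sampling noise and knockdown 3 stands apart.

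Counts were tested with edgeR 4.0.16 (R 4.3.3): the default expression filter, which removed no row, TMM scaling, a quasi-likelihood fit with the group as the only term, and Benjamini-Hochberg adjustment over 13451 rows at 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. Fold changes in words are ratios from the fitted log2 fold change. CPM are counts-per-million with TMM scaling. The 28 gene lists were fixed before the data were examined and were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01, adjusted over the lists), with camera with an estimated correlation and with fry beside it. No list was past the threshold with an estimated correlation or by fry's directional test, while 21 of 28 were by fry's mixed test of change in either direction, which does not compare a list with other genes. A member is counted as higher or lower at a genome-wide adjusted p under 0.05, and also adjusted over the list alone. The lists cover U2 snRNP and SF3 genes, other spliceosome proteins, SR proteins and kinases, Notch machinery and targets, cell cycle, p53, apoptosis, migration, hepatocyte, stress, sterol, glycolysis, Wnt, inflammatory, immediate early, ribosomal, mitochondrial and histone genes and markers of other liver cell types.

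Genes named by rule, set before the data were examined, are SF3A3, the 12 protein-coding genes with the largest increase and the 12 with the largest decrease among those past the threshold with at least 10 CPM in the higher group and no overlap between the groups, up to 4 members of each list, and a short fixed set. Some genes that the rule takes are not reported here. The 3 libraries per group were compared for SF3A3 alone with a two-sided exact permutation test. In simulated counts for 13451 rows with the real means, dispersions and library sizes, 30 of 100 genes changed 1.5-fold and 61 of 100 changed 2-fold were recovered, with 7 false calls. These 6 libraries may therefore leave many changes of up to 2-fold undetected. The simulation changed 200 genes 1.5- or 2-fold, fewer than the 603 rows called in the real data. Recovery after adjustment depends on how many genes change, so the share recovered may differ in the real data. The shares of depth, spread and number of libraries in the loss were not tested. Reads of overlapping or near-identical genes cannot be told apart here, and the strand setting of the counting is not given in the sources used here.

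Alternatives set in advance were DESeq2's size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, protein-coding rows alone, the replicate number as a block, each library left out, a test against a log2 fold change of 0.58, and the other set tests. Robust dispersion estimation and rows with Ensembl identifiers alone were added after the data were seen. Other tests used implied transcript lengths (count over FPKM, limma, rows with at least 50 counts in every library), intron number, transcript length and GC content of the longest transcript of each gene in GENCODE, and the pathway annotation deposited with the table. In a simulation of the length test, 200 of 200 genes shifted by 0.5 on the log2 scale were recovered among 11319, with 15 false calls. Gene annotation was read with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.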

Results

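Messenger RNA was sequenced from HepG2 cells, an established human liver tumour line, after transfection with small interfering RNA (siRNA). One group of 3 libraries received a negative control siRNA. The other group of 3 libraries received an siRNA against SF3A3, which encodes a subunit of the SF3A complex of the U2 small nuclear ribonucleoprotein (U2 snRNP), the particle that recognises the branch point of introns. Both siRNAs were used at 50 nM for 48 h. The libraries held between 31272558 and 35361182 counts each, spread over 13451 gene rows. The series is about proliferation, migration and Notch signalling in hepatocellular carcinoma cells, and the comparison asks which transcripts differ when SF3A3 is targeted. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

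SF3A3 mRNA was low in 2 of the 3 libraries labelled knockdown and close to the control level in the third. SF3A3 (ENSG00000183431, GRCh38 chromosome 1, 37956975 to 37990921, minus strand) stood at 119, 106 and 126 counts-per-million (CPM) in the controls. It stood at 31.8 and 32.3 CPM in knockdown 1 and 2, which is 27.1% and 27.6% of the control mean, and at 93.8 CPM, or 80.0%, in knockdown 3. The group means were 117 ± 10.1 CPM in the controls and 52.6 ± 35.6 CPM in the knockdown (SD, n = 3 each). The log2 fold change of -1.16 (SE 0.43) did not pass the threshold (edgeR quasi-likelihood test, adjusted p = 0.164). Every library labelled knockdown lay below every control, and the two-sided exact permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow. Without knockdown 3 the log2 fold change was -1.87 (adjusted p = 0.003), and over the 16 alternatives tried the adjusted p ran from 0.003 to 0.337. Because of this level, every direction given for the knockdown refers to the libraries labelled knockdown, of which knockdown 3 kept most of its SF3A3 mRNA.

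Other subunits of the U2 snRNP moved with the labels. SF3B2, a subunit of the SF3B complex that binds beside SF3A, rose from 203 ± 2.95 to 299 ± 6.42 CPM (log2 fold change 0.56, SE 0.05, adjusted p = 0.011). SNRPA1, which encodes a U2-specific protein, rose by a log2 fold change of 0.66 (adjusted p = 0.019), PHF5A by 0.53 (adjusted p = 0.032), SF3B3 by 0.44 (adjusted p = 0.037) and the helicase DDX46 by 0.36 (adjusted p = 0.048), all by edgeR. DDX46 lies outside the fixed naming rule and was added after its value was seen. These 5 were the members past the threshold among 23 U2 snRNP and SF3 genes tested, none fell, and 6 rose when adjusted over the list alone. The fit without knockdown 3 had 6 of the 23 higher and 2 lower. The list as a whole lay higher (camera, mean log2 fold change 0.11, adjusted p = 0.002), with adjusted p = 0.684 with an estimated correlation and 0.075 without knockdown 3. Like SF3A3, SF3A1 was low in knockdown 1 and 2, at 62.9 and 58.7 CPM, and nearer the controls in knockdown 3, at 114 CPM. The controls stood at 123.65, 120.3 and 119.2 CPM, and its log2 fold change of -0.63 (SE 0.25) did not pass (edgeR, adjusted p = 0.188). Without knockdown 3 it was -0.99 (adjusted p = 0.003). SF3A2 (0.12, adjusted p = 0.284) and SF3B1 (0.05, adjusted p = 0.764) did not pass either.

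**Figure D1:**
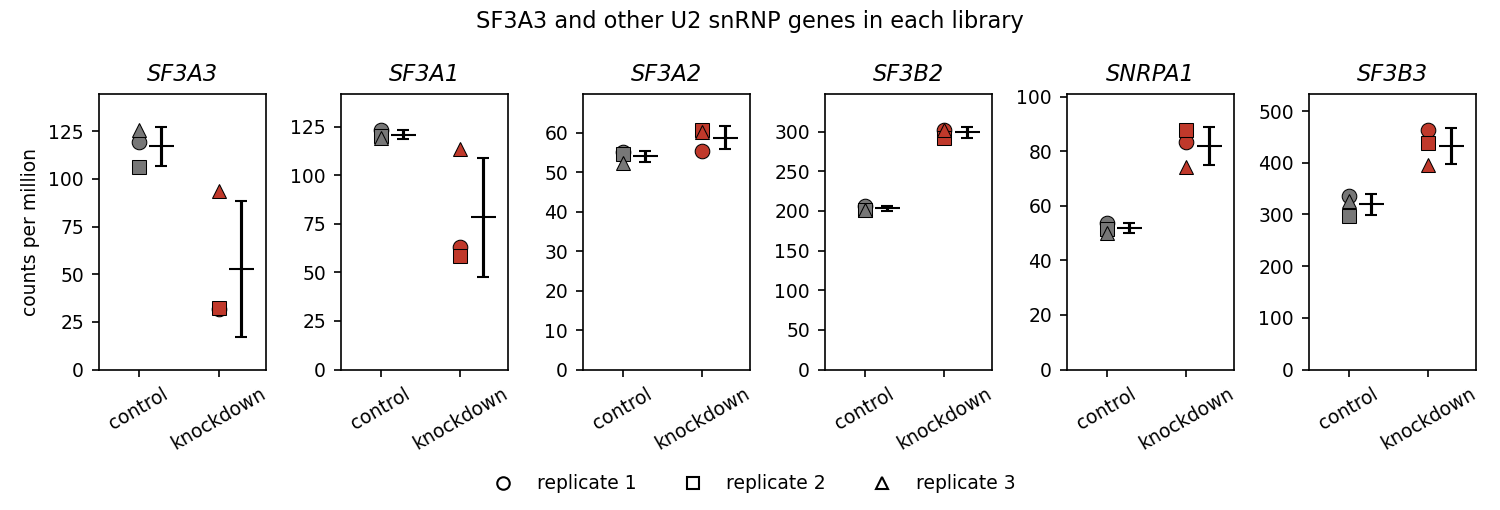
Level of SF3A3 and 5 other U2 snRNP genes in counts-per-million (vertical axis, from 0) in the 3 control and 3 knockdown libraries, 1 symbol per library, with the group mean and SD (n = 3) as a bar beside the points. SF3A3 and SF3A1 in knockdown 3, at 93.8 and 114 CPM, lie near the controls, while SF3B2, SNRPA1 and SF3B3 lie above the controls in every knockdown library.

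Across the transcriptome, 603 of 13451 gene rows differed between the groups. In the libraries labelled knockdown 343 were higher and 260 lower, with median log2 fold changes of 0.43 and -0.49, and 11 of the higher and 37 of the lower rows changed at least 2-fold. Most changes were therefore smaller than 2-fold. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3215 rows had an unadjusted p under 0.05. With scaling to library size alone, 44.5% of 629 calls were higher, against 56.9% of the 603. The count rested on the set of libraries: leaving out control 1, control 2 or control 3 left 5, 9 and 13 genes, leaving out knockdown 1 or knockdown 2 left 10 and 11, and leaving out knockdown 3 gave 2301, which included all 603. Of 61 named genes past the threshold, 61 stayed past it without knockdown 3 and 1 to 3 without any other library. DESeq2 called 2547 rows on the same counts. Of 89 named genes 8, which are APOBEC3B, PHACTR2, HELLS, MDM2, POLD3, HSP90B1, RPL4 and RPL3, have an exon that overlaps another gene on the same strand, so their counts are uncertain.

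The genes with the largest increases by the fixed naming rule were led by PEG10, a retrotransposon-derived imprinted gene, which rose from 554 ± 60.4 to 1255 ± 84.0 CPM (log2 fold change 1.18, SE 0.09, adjusted p = 0.011, edgeR). The hyaluronan-binding protein gene HABP4 rose 2.21-fold (adjusted p = 0.014). FOS, a subunit of the AP-1 transcription factor, rose 2.10-fold from 25.0 ± 1.25 to 52.5 ± 14.04 CPM (adjusted p = 0.034). The stress-induced nuclear protein gene NUPR1, the arginine methyltransferase gene PRMT6, the somatostatin receptor gene SSTR5 and the tropomyosin gene TPM4 rose 1.97-, 1.96-, 1.95- and 1.93-fold. HSDL2, FGA, BCL7A and PHACTR2 rose 1.85- to 1.93-fold. In all 11 of these genes, each of the 3 libraries labelled knockdown lay above each of the 3 controls, which is part of the naming rule.

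The largest decreases by the same rule were those of TIE1, a receptor tyrosine kinase of endothelial cells, from 14.6 ± 2.87 to 5.22 ± 1.82 CPM (log2 fold change -1.49, SE 0.27, adjusted p = 0.037, edgeR), and of the cytidine deaminase gene APOBEC3B, from 11.8 ± 0.48 to 4.67 ± 0.76 CPM (-1.33, SE 0.15, adjusted p = 0.019). APOBEC3B also has close paralogs that could share its reads. GRIPAP1, the fatty acid hydroxylase gene CYP4F2 and the receptor tyrosine kinase gene AXL fell by 1.10, 1.09 and 1.08 on the log2 scale. TK1, the thymidine kinase of the DNA synthesis phase, fell with the least spread, from 111 ± 2.39 to 59.7 ± 1.14 CPM (log2 fold change -0.90, SE 0.05, adjusted p = 0.006). TNS4, B3GAT3, UHMK1 and the chemokine gene CX3CL1 fell by 0.82 to 0.86 on the log2 scale. OIP5, a centromere gene, fell from 14.7 ± 1.88 to 8.42 ± 0.78 CPM and CABLES2 from 27.0 ± 4.30 to 15.6 ± 1.06 CPM.

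**Figure D2:**
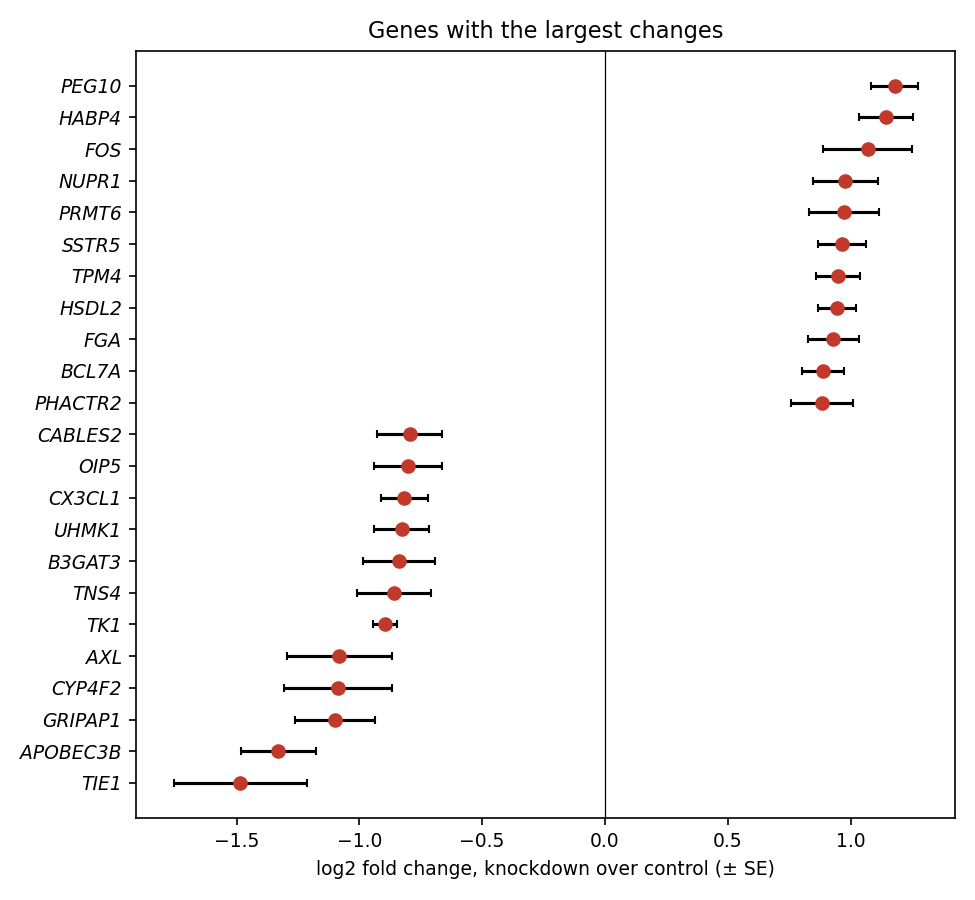
Log2 fold change of knockdown over control (horizontal axis) with its standard error (bars) for 11 genes with the largest increases and 12 with the largest decreases by the fixed rule, 3 libraries per group. PEG10 at 1.18 and TIE1 at -1.49 mark the extremes.

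Genes of Notch signalling, the pathway that the series names, passed the threshold in 2 cases, LFNG and MYC. LFNG, a glycosyltransferase that modifies Notch receptors, fell from 4.16 ± 0.81 to 1.53 ± 0.33 CPM (log2 fold change -1.44, SE 0.26, adjusted p = 0.037, edgeR). It was the 1 member past the threshold among 47 Notch receptor, ligand and machinery genes tested, and also the 1 adjusted over the list alone. In the fit without knockdown 3, which called 2301 rows in all, 4 of the 47 were lower and 2 higher. NOTCH3 stood at 5.09 ± 0.80 CPM in the controls and 2.56 ± 0.65 CPM in the knockdown, a log2 fold change of -0.99 that did not pass (SE 0.25, adjusted p = 0.076), while the authors' deposited table gives it an adjusted p of 0.002. NOTCH1 (-0.35, adjusted p = 0.300), NOTCH2 (-0.33, adjusted p = 0.160) and the ligand gene JAG1 (-0.19, adjusted p = 0.335) did not pass, and without control 2 NOTCH1 was at -0.17 and JAG1 at -0.08. Of 13 Notch target genes tested, MYC rose (0.33, SE 0.06, adjusted p = 0.042) and no other passed. Adjusted over the list alone, 1 was higher, which was MYC, and 1 lower, which was NOTCH3, also a member of this list. The fit without knockdown 3 called 2 of the 13 higher and 2 lower. The targets HES1 (-0.14, adjusted p = 0.286) and HEY1 (-0.33, adjusted p = 0.438, and -0.59 without knockdown 3, adjusted p = 0.077) did not pass. Neither list was past the threshold by camera (machinery adjusted p = 0.481, targets adjusted p = 0.468, and 0.928 and 0.761 with an estimated correlation). The mixed test of fry, which asks whether members change in either direction, gave both lists an adjusted p under the threshold (0.008 and 0.014), as it did 21 of the 28 lists. The median log2 fold change of the machinery list was 0.0001 and its mean -0.12. The series names this pathway and may have chosen it from these libraries, so the lists are not taken as independent evidence. DLL1 and VIM, 2 genes fixed in advance, had no row to test.

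The lists of G2 and M phase genes and of S phase genes lay lower in the libraries labelled knockdown by camera at the preset correlation, with adjusted p = 0.684 and 0.761 with an estimated correlation. Among 54 genes of the G2 and M phases, 8 fell and none rose (18 and 1 without knockdown 3), and 14 fell when adjusted over the list alone. CKS1B, a cofactor of cyclin-dependent kinases, fell from 55.7 ± 2.75 to 40.7 ± 1.86 CPM (log2 fold change -0.45, SE 0.07, adjusted p = 0.025, edgeR). The mitotic kinase gene AURKB fell by 0.46, CDCA8 by 0.36 and the tubulin gene TUBB4B by 0.37 on the log2 scale. The list mean was -0.20 (camera adjusted p = 1.12e-09), at -0.12, -0.15 and -0.37 in knockdown 1, 2 and 3. Among 42 S phase genes, HELLS (-0.57) and the polymerase subunit gene POLD3 (-0.49) fell. Of the 42 genes 2 fell and 1 rose (9 and 1 without knockdown 3), and 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.002). The S phase list mean was -0.124, -0.207 and -0.166 in knockdown 1, 2 and 3, and control 2, at -0.123, lay at the level of knockdown 1. CCND1 (-0.25, adjusted p = 0.347, and -0.10 without knockdown 3) and the inhibitor gene CDKN1A (-0.12, adjusted p = 0.653, and 0.02 without knockdown 3) did not pass. None of the 7 replication-dependent histone genes with a row passed, with H2AC6 at -0.20 and H1-2 at 0.11 (camera adjusted p = 0.732). The mean of that list was -0.14, and -0.57 without knockdown 3 (camera adjusted p = 0.348), at -0.60, -0.41 and 0.25 in knockdown 1, 2 and 3. In the pathway annotation deposited with the table, 117 cell cycle genes held 2 that rose and 1 that fell (mean -0.05, camera adjusted p = 0.421).

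Few apoptosis and p53 genes passed the threshold in the full comparison. The initiator caspase gene CASP8 and the cytochrome c gene CYCS rose, the latter from 132 ± 5.47 to 178 ± 5.10 CPM (log2 fold change 0.43, SE 0.05, adjusted p = 0.022, edgeR). Of 35 apoptosis regulators 3 rose and none fell (6 and 1 without knockdown 3), and 4 rose when adjusted over the list alone (camera adjusted p = 0.061). Among 32 p53 target genes the kinase gene PLK2 rose (0.42, adjusted p = 0.035) and MDM2, which encodes the ligase that degrades p53, fell (-0.23, adjusted p = 0.049), with 2 in each direction when adjusted over the list alone (camera adjusted p = 0.718). The median of that list was 0.01 and its mean -0.01, and the fit without knockdown 3 had 6 of the 32 higher and 2 lower.

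In the list of 29 migration and epithelial-mesenchymal transition genes, 2 passed and both fell. CDH1, the epithelial cadherin, fell from 109 ± 3.15 to 78.8 ± 3.997 CPM (log2 fold change -0.47, SE 0.06, adjusted p = 0.020, edgeR), and the integrin gene ITGA3 fell from 5.20 ± 0.11 to 1.602 ± 0.48 CPM (-1.70, SE 0.25, adjusted p = 0.025). The former marks epithelial cells and the latter encodes a receptor for laminins. CDH2, the neural cadherin, was at 1.18 ± 0.30 and 1.39 ± 0.39 CPM (adjusted p = 0.718). Adjusted over the list alone, 3 fell and 2 rose (camera adjusted p = 0.036, and adjusted p = 0.761 with an estimated correlation). The adjusted p of the list was 0.339 without control 2, 0.148 without knockdown 1 and 0.238 without knockdown 3. That last fit had 4 of the 29 lower and 2 higher.

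The lists of heat shock and immediate early genes lay higher by camera at the preset correlation, with adjusted p = 0.684 for each with an estimated correlation. Of 23 heat shock genes 5 rose (10 without knockdown 3) and none fell, and 7 rose when adjusted over the list alone. The mitochondrial chaperonin gene HSPD1 rose from 1566 ± 64.7 to 2233 ± 44.6 CPM (log2 fold change 0.51, SE 0.05, adjusted p = 0.011, edgeR), and HSPH1, HSP90AA1 and FKBP4 rose by log2 fold changes of 0.56, 0.43 and 0.38, with AHSA1, named after its value was seen, as the fifth. The list mean was 0.23 (camera adjusted p = 1.93e-06). Of 27 immediate early genes FOS and MYC rose and none fell (7 and 0 without knockdown 3), and 3 rose when adjusted over the list alone (list mean 0.28, camera adjusted p = 3.37e-04). Of 17 NF-kappaB and inflammatory genes none passed, while 3 fell when adjusted over the list alone and 5 fell without knockdown 3. ICAM1 was at 420 ± 35.3 and 321 ± 22.8 CPM (-0.39, adjusted p = 0.054), and SOD2 at -0.31 (adjusted p = 0.197). Without knockdown 3 ICAM1 was at -0.33 (adjusted p = 0.039) and SOD2 at -0.48 (adjusted p = 0.007). The list lay lower as a whole (mean -0.23, camera adjusted p = 0.004, and adjusted p = 0.684 with an estimated correlation).

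Hepatocyte genes moved both ways. The fibrinogen chain genes FGA and FGG rose by log2 fold changes of 0.93 and 0.63, and ALB, the albumin gene, rose from 11501 ± 554 to 13591 ± 480 CPM (0.24, SE 0.05, adjusted p = 0.040, edgeR). The coagulation factor gene F10 fell by 0.54 and the apolipoprotein gene APOC3 by 0.49 on the log2 scale. In all, 5 of 37 hepatocyte secreted protein genes rose and 2 fell (7 and 7 without knockdown 3), with 8 and 4 adjusted over the list alone (camera adjusted p = 0.062). AFP, the fetal albumin gene, did not pass (0.09, adjusted p = 0.680). Of 25 hepatocyte transcription factor genes, PPARA (0.50), CEBPD (0.60) and PROX1 (0.41) rose and none fell, and 4 rose when adjusted over the list alone (camera adjusted p = 0.112). The fit without knockdown 3 had 4 of the 25 higher and 2 lower.

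Sterol, chaperone and glycolysis genes separated knockdown 3 from the other knockdown libraries. The mean log2 level of 24 cholesterol synthesis genes, relative to the controls, was -0.34 in knockdown 1, -0.40 in knockdown 2 and 0.39 in knockdown 3. None of the 24 passed in the full comparison, nor adjusted over the list alone (camera adjusted p = 0.382), while without knockdown 3 14 of them were lower (camera adjusted p = 4.98e-12). The 22 unfolded protein response chaperone genes had means of -0.18, -0.20 and 0.09, with none past the threshold or adjusted over the list alone (camera adjusted p = 0.185) and 8 lower without knockdown 3 (camera adjusted p = 3.28e-04). HSPA5, the main chaperone of the endoplasmic reticulum, stood at 1029, 988 and 1589 CPM in knockdown 1, 2 and 3 against 1401 ± 105 CPM in the controls, and HSP90B1 at 1240, 1239 and 1618 CPM against 1557 ± 30.3 CPM. Both passed without knockdown 3 (log2 fold changes -0.48 and -0.33, adjusted p = 0.013 and 0.007). Among 32 glycolysis and hypoxia genes PGAM1 (0.29) and PFKL (0.38) rose, also adjusted over the list alone. The list mean was -0.07, 0.01 and 0.48 in the 3 knockdown libraries, and the camera adjusted p of 0.025 became 0.900 without knockdown 3, 0.122 without control 1 and 0.869 with an estimated correlation.

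**Figure D3:**
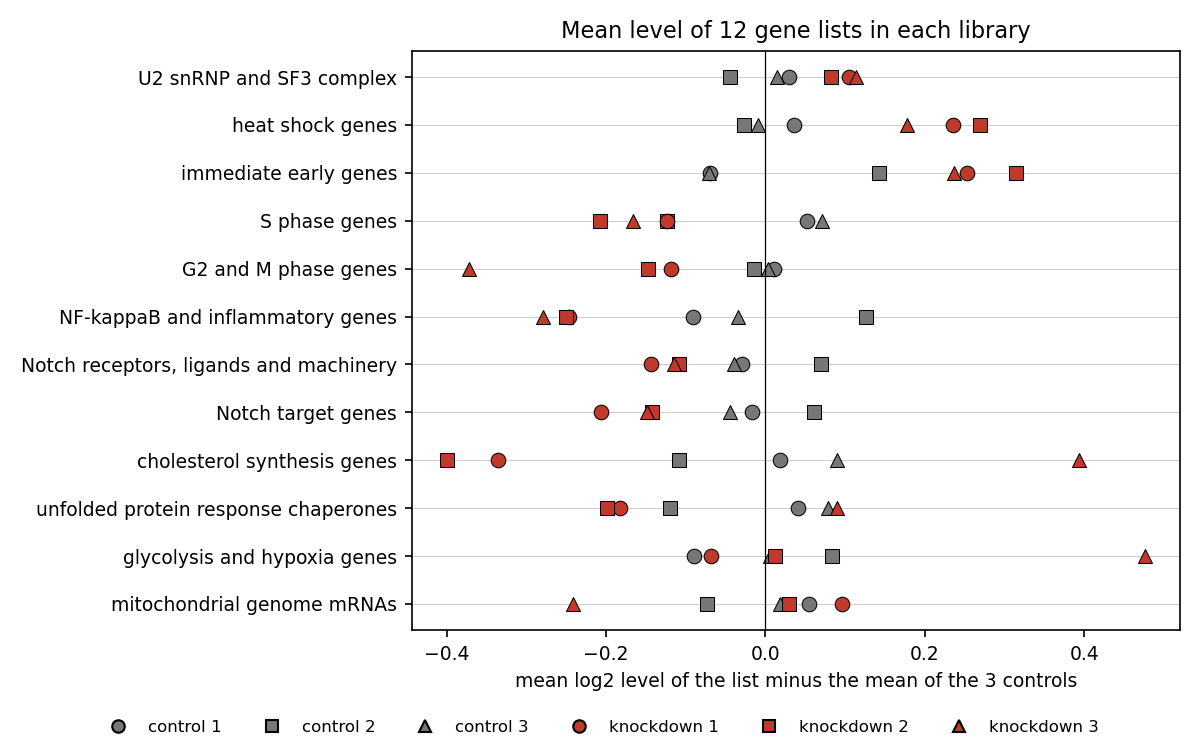
Mean log2 level of 12 of the fixed gene lists in each library, minus the mean of the 3 controls (horizontal axis), 1 symbol per library (controls grey, knockdown red). Heat shock and immediate early genes lie to the right in all 3 knockdown libraries, whereas the cholesterol synthesis genes lie at -0.34 and -0.40 in knockdown 1 and 2 and at 0.39 in knockdown 3.

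Few members of the remaining lists passed the threshold. Among 43 other spliceosome proteins PLRG1 (0.61) and SLU7 (0.33) rose, none fell, and the same count rose adjusted over the list alone (list mean 0.10, camera adjusted p = 0.025, and adjusted p = 0.761 with an estimated correlation, 0.226 without control 2 and 0.124 without knockdown 3). CLK1, a kinase of splicing regulators, was the 1 of 20 SR protein and kinase genes to rise (0.51), also adjusted over the list alone (camera adjusted p = 0.421). NUPR1 was the 1 of 32 ATF4 target genes to rise, also adjusted over the list alone (camera adjusted p = 0.395). The fit without knockdown 3 had 2 ATF4 target genes higher and 6 lower (camera adjusted p = 0.643). It had 4 of the other spliceosome proteins higher and 2 lower, and 2 of the SR protein and kinase genes higher and 3 lower. Of 21 Wnt target genes MYC rose and NOTUM, a secreted Wnt inhibitor, fell (-0.47), both also adjusted over the list alone (camera adjusted p = 0.625). None of 32 interferon-stimulated genes passed, with IFITM3 at 0.11 and BST2 at 0.24, or 0.36 without knockdown 3, adjusted p = 0.008 (camera adjusted p = 0.841), nor did any of 78 cytosolic ribosomal protein genes, with RPL4 at -0.02 and RPL3 at -0.01 (camera adjusted p = 0.605). MT-ND5 fell by 0.53 on the log2 scale as the 1 of 13 mitochondrial genome mRNAs past the threshold, with 2 lower adjusted over the list alone (camera adjusted p = 0.733). Mitochondrial mRNA made up 10.2% to 10.7% of the counts in the controls, 11.4% and 10.7% in knockdown 1 and 2, and 9.13% in knockdown 3.

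Few marker genes of other liver cell types passed the threshold. TIE1 and STAB1 (-1.57, adjusted p = 0.043) fell among 7 endothelial marker genes with a row, and 3 fell adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.684 with an estimated correlation, 0.116 without knockdown 3 and 0.069 with a filter of 5 CPM). The mean of the endothelial list was -0.638, against -0.676 without knockdown 3 and -0.699 with that filter. STAB1 stood at only 1.43 ± 0.28 CPM in the controls. LAPTM5 fell from 8.75 ± 1.44 to 3.09 ± 0.25 CPM among 7 leukocyte marker genes, of which 2 fell adjusted over the list alone (camera adjusted p = 0.254). None of 8 cholangiocyte and 5 stromal marker genes passed, while 1 stromal gene was lower adjusted over the list alone (camera adjusted p = 0.931 and 0.732). The cholangiocyte markers SPP1 and KRT19 stood at 1033 and 555 CPM in the controls with log2 fold changes of -0.07 and -0.10, and the stromal markers ACTA2 and TAGLN at 58.8 and 22.5 CPM with 0.09 and 0.14. Without knockdown 3 SPP1 passed at -0.19 (adjusted p = 0.025), and ACTA2 and TAGLN were at 0.23 and 0.44 (adjusted p = 0.060 and 0.063).

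The authors' deposited table holds their own comparison of the same counts. It gives an adjusted p under 0.05 to 2535 rows, 1357 higher and 1178 lower, and includes all 603 rows called here, each in the same direction, with 1932 more. It marks 54 rows as up and 108 as down, all with a log2 fold change of at least 1 in size and an unadjusted p under 0.05, and 48 of these were called here. The log2 fold change of SF3A3 in the authors' deposited table is -1.15, with an adjusted p of 0.116.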

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

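Robust dispersion and Ensembl rows alone were chosen after the data were seen. All 603 genes kept their direction where tested. The counts were reused, and groups without overlap must keep it with 1 library left out. The count of 603 genes (343 higher, 260 lower) became 2547 with DESeq2 (1369 higher, 1178 lower), 932 among protein-coding rows (421 lower) and 3 when tested against a log2 fold change of 0.58. Ensembl rows gave 423 lower. The causes were not tested, although the last 2 feature sets also changed the number of rows. With the replicate block 0 genes passed (0 higher, 0 lower, by edgeR, with 3269 at an unadjusted p under 0.05), against 603 without it. The replicate numbers share no more than a number: deviations from the group means correlated at 0.009, 0.026 and 0.033 between same-numbered libraries, each of which correlated best with its own number. Leaving out 1 library gave 5 to 2301 genes (4 to 1162 higher, 1 to 1139 lower), the lowest without control 1 and the highest without knockdown 3, and fewer libraries enter each of these fits. Of 61 named genes past the threshold, 58 to 61 stayed past it under other scaling, tools, dispersions and features, apart from 59 of 59 tested with the stricter filter, and 61 did so without knockdown 3, against 1 to 3 without any other library and 0 with the replicate block. The SF3A3 log2 fold change ran from -1.87 without knockdown 3 to -0.89 without knockdown 1. The overlap with the authors' deposited table was 603 genes and 48 where both required a 2-fold change. No low-count filter gave the same 603. Pseudocounts and filters for normalized values did not apply to counts.

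Of 28 lists, 10 passed with the preset correlation and 0 with an estimated correlation or with fry's directional test, while 21 passed fry's mixed test of change in either direction. Over the leave-one-out fits 8 to 12 passed. Without knockdown 3 the U2 snRNP and SF3 complex, other spliceosome, migration, endothelial and glycolysis lists no longer passed, and the chaperone, cholesterol and ribosomal protein lists did. Of the lists lost, the U2 snRNP and SF3 complex (mean 0.107 to 0.091), other spliceosome proteins (0.097 to 0.088), migration and EMT genes (-0.179 to -0.162) and endothelial cell markers (-0.638 to -0.676) kept most of their mean, whereas glycolysis and hypoxia genes did not (0.172 to -0.031). Other spliceosome (mean 0.058) and migration (-0.090) no longer passed without control 2, glycolysis (0.130) without control 1 and migration (-0.125) without knockdown 1. Lists short of the threshold passed in some fits: hepatocyte secreted proteins without control 3 (adjusted p = 0.015), knockdown 1 (0.034) or knockdown 2 (0.013) and with DESeq2 (0.0495), apoptosis regulators without control 2 (0.025) and with DESeq2 (0.048), hepatocyte transcription factors without knockdown 2 (0.014) and unfolded protein response chaperones without control 2 (0.017). The 2 Notch lists stayed short of the threshold in every camera fit and by fry's directional test, and passed fry's mixed test (0.008 and 0.014). Directions turned for values that had not passed. Cytosolic ribosomal proteins, at a mean of 0.01, gave -0.0205 with library size only, and cholangiocyte markers, at 0.08, gave -0.018 with the stricter filter. Leaving out 1 library gave means of -0.027 to 0.0565 for cytosolic ribosomal proteins, -0.0533 to 0.0274 for p53 target genes, -0.0207 to 0.135 for hepatocyte transcription factors, -0.0696 to 0.0196 for interferon-stimulated genes, -0.0162 to 0.113 for ATF4 target genes, -0.371 to 0.079 for cholesterol synthesis genes, -0.0311 to 0.278 for glycolysis and hypoxia genes, which had passed, -0.105 to 0.0177 for Wnt target genes and -0.0963 to 0.0619 for mitochondrial genome mRNAs. Among single genes the log2 fold change ran from -0.0363 to 0.0998 for SF3B1, -0.239 to 0.0163 for CDKN1A, -0.0079 to 0.402 for CDH2, -0.0111 to 0.16 for AFP, -0.0188 to 0.004 for RPL3, -0.372 to 0.124 for H2AC6 and -0.107 to 0.445 for TAGLN. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split with 603 genes, called that many, and the highest other called 5. With 10 splits no share under 0.05 can be reached. With the depth, spread and number of these libraries, 30 of 77 simulated genes of at least 10 CPM changed 1.5-fold were recovered. Which of the 3 limits this was not tested.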

Other observations

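The tests of knockdown 3 and of the largest fold changes were chosen after the results were seen, and those of introns, GC content, length and implied transcript length before. Pathway annotation deposited with the table described gene groups outside the fixed lists, and 5 of 297 pathways passed with camera at the preset correlation, none with an estimated correlation. Genes of fatty acid degradation were higher (mean log2 fold change 0.15, camera adjusted p = 0.002, and adjusted p = 0.947 with an estimated correlation), with ACAT1, ADH6, ADH5 and EHHADH as the 4 of 35 past the threshold (edgeR log2 fold changes 0.51, 0.75, 0.32 and 0.72). Ribosome biogenesis genes were higher too (camera adjusted p = 0.025, and adjusted p = 0.947 with an estimated correlation), with 5 of 73 risen, among them SBDS (0.46), a ribosome maturation factor, and the nucleolar gene GNL3 (0.40). DNA replication genes were lower (camera adjusted p = 0.010, and adjusted p = 0.947 with an estimated correlation), with the polymerase genes POLD3, POLD1 (-0.37) and POLE (-0.34) as the 3 of 38 that fell. These genes were named after their values were seen.

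Matrix receptor and adhesion genes were lower as groups. Of 46 extracellular matrix receptor genes 4 fell, which were ITGA3, the laminin genes LAMC3 (-1.07) and LAMA5 (-0.38) and the proteoglycan gene AGRN (-0.40), while RELN rose (0.64) (camera adjusted p = 0.022, and adjusted p = 0.947 with an estimated correlation). Of 62 cell adhesion molecules 6 fell, among them CDH1, NECTIN1 (-0.31) and the immune checkpoint gene VSIR (-2.21) (camera adjusted p = 0.039, and adjusted p = 0.947 with an estimated correlation).

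Knockdown 3 kept 80.0% of the control SF3A3 mRNA yet moved in part with the other knockdown libraries. On 300 genes picked without it and without 1 control, the library moved by 0.467 of the change of the others, against 0.037 to 0.129 for the control left out, which argues against a mislabelled control. A response in proportion to the linear loss of SF3A3 would give a share of 0.275, and to its log2 loss a share of 0.172. Over 12 pairings of separate libraries the share, taken from log2 changes, was 0.398 (SD 0.227). That spread is too wide to decide, and the pairings reuse the same 6 libraries, so their shares are not independent. Proportion to SF3A3 loss does not account for the cholesterol synthesis genes, whose mean in knockdown 3 lay at 0.393, above the controls, while it was -0.34 and -0.40 in the others. The G2 and M phase list (-0.118, -0.147 and -0.372 in knockdown 1, 2 and 3) and the glycolysis list also moved farthest in knockdown 3. The heat shock list (0.235, 0.269 and 0.177) moved least there. A difference between the groups other than SF3A3, such as off-target silencing, culture or library batch, cannot be told apart from the knockdown. Per the titles and the protocol every knockdown library had an siRNA against SF3A3, and no batch is labelled. The treatment labels of knockdown 2 and 3 name SF3A4 and SF3A5, so a different treatment of knockdown 3 also stays open. Knockdown 2, labelled SF3A4, held 27.6% of the control SF3A3 mRNA. The called genes moved by a median of 0.43 in knockdown 3, against 0.46 and 0.45 in knockdown 1 and 2, though they were chosen with it.

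Some of the largest fold changes may come from reads assigned to another of several overlapping gene models. Of 12 called rows changed at least 4-fold, 10 were assembled models, overlapping models or Ensembl rows without a symbol, against 3407 of 13451 tested rows (Fisher's exact odds ratio 14.77, 95% interval 3.15 to 138.72). An assembled model annotated as DAXX went from 0 counts in each control to 247 to 341 in the knockdown libraries. Its sister model went from 264 to 283 down to 11 to 29, and their sum was 823 in the controls and 972 in the knockdown. In the pair annotated as MRM1 one model went from 361 to 0 counts and the other from 84 to 303. The sum of that pair fell from 445 to 303, so within the pair the loss is not matched by the gain. Outside the pairs, the row named MRM1 went from 416 to 504 counts and the row named DAXX from 1176 to 1016. Neither of these 2 rows passed (edgeR, adjusted p = 0.544 and 0.554). A model that spans several genes on chromosome 12 (55757275 to 55827546) and is annotated as DNAJC14 went from 369, 358 and 422 counts to 13, 10 and 3, while DNAJC14 itself had a log2 fold change of 0.39 (adjusted p = 0.067, edgeR). Whether such shifts reflect a change in transcript structure with less SF3A3 was not tested, since junction reads were not analysed here.

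A hypothesis from the role of SF3A3 is that genes with more introns fall. Across 12151 protein-coding genes, which are not independent replicates, the partial Spearman correlation of intron number with log2 fold change, given length, GC content and level, was -0.07 (permutation p = 1e-04, the smallest the permutations can give, and adjusted p = 1.25e-04 over 5 relations), too small to decide either way by the bounds set, and it was -0.062, -0.076 and -0.026 in knockdown 1, 2 and 3. Transcript GC content correlated at -0.124 (-0.039, -0.1 and -0.178 in knockdown 1, 2 and 3) and mean level at 0.175 (0.120, 0.125 and 0.164), so a bias with GC or level stays open, while transcript length, at 0.005, argues against a length bias shared by the knockdown libraries. If isoform use had changed widely, the implied transcript length of many genes might differ, but 5 of 11319 genes passed (limma, with 809 at an unadjusted p under 0.05), among them POLR2E and UBE2G1, against up to 4 in other splits of the libraries, which gives little sign of it.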
